A study of Mus musculus with 2 samples.

How the data were processed

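The data were RNA sequencing of mouse bone marrow progenitors that carried Hoxa9-ER and Meis1, in 2 samples, 4OHT and EtOH, each made of 2 biological replicates. Per the labels' protocols, RNA was purified on columns with DNase digestion, and libraries were made with a TruSeq RNA kit. The submitters' processing notes list CASAVA 1.8.2, Bowtie2 2.0.0.7, Cuffdiff 2.0.2 and the mm9 genome build. The gene annotation, the order of the steps, the strand setting and the scaling between libraries are not given in the sources used here.

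The deposited table held 1 row for each of 23235 gene names. Per the file headers, the authors gave an FPKM value per condition (fragments scaled to transcript length and to mapped fragments), a p-value and a q-value of the comparison of EtOH with 4OHT, a test status and a ratio of EtOH over 4OHT. The authors tested 11865 rows, left 11197 untested, marked 152 as having too little data and had a failed test in 21. The deposited q-values equalled a Benjamini-Hochberg adjustment of the deposited p-values over the tested rows to within 1.7e-06. The deposited ratio differed from EtOH over 4OHT by over 1% in 18 rows and was used only for the alternative counts of called genes. The authors' own second call added a ratio of at least 1.5 in either direction. The table had 89 rows that name several genes and 25 names that a spreadsheet had turned into dates, which were left as they are.

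Each condition had 1 FPKM value, so no test of this work was possible across conditions, and the calls are those of the authors' deposited table at q of at most 0.05. FPKM values given once per condition hide the spread between replicates, which could enter only through the authors' test. Whether that test took the replicates as separate libraries is not known here. FPKM values are relative to the whole library, so a rise of abundant RNAs lowers the values of all others. FPKM values do not give read totals. Among genes with loci of 2 to 4 kb, FPKM was multiplied by locus length, introns included, and the lowest step was taken as the products in a fixed low window. It had a median of 20.8 over 26 genes in 4OHT and 22.8 over 18 genes in EtOH. The lowest products inside that window were 19.8 and 21.0. If such a step is 1 fragment, 1 FPKM of a 1 kb transcript rests on about 48.1 fragments in 4OHT and 43.9 in EtOH. The depth is otherwise unknown, and no counting interval is given. Rows listed at 0 numbered 8015 in 4OHT and 7818 in EtOH. Among called genes, 16 were listed at 0 in 4OHT and 1 in EtOH, and no fold is given for them.

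From the FPKM values, log2((FPKM EtOH + 1)/(FPKM 4OHT + 1)) was computed for each gene. Counts of genes changed at least 2-fold and all list values used genes of at least 1 FPKM in either condition. Before the data were examined, 27 lists with 811 entries were fixed, 20 of processes or cell states and 7 of other cell types that the culture could hold. Older symbols were matched through a RefSeq gene table used for names alone. Ly6g and Ear12 were not analysed here. For each list the median change was placed among the medians of 10000 random lists of the same size, drawn from 20 bins of mean expression. A list was said to stand apart at or under percentile 2.5 or at or over percentile 97.5, and lists with under 5 measured members got no percentile. These percentiles describe these libraries and are no p-values. Counts adjusted over the list alone came from a Benjamini-Hochberg adjustment of the authors' deposited p-values within the list.

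The genes named were also set by a rule fixed beforehand. It took Hoxa9 and Meis1, then the 12 largest rises and 12 largest falls among called genes of at least 5 FPKM in either condition, skipping rows of several genes. From each list it took up to 4 called members with the largest change. The rule named 108 genes or entries, of which some are not reported here, and genes outside it are said to have been named after their values were seen, apart from the other genes of the Hoxa cluster and list members that did not pass. Esr1 came through the estrogen response list.

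Sequence shared between genes was measured as the share of a gene's 50-base words found in transcripts of other genes in GENCODE M21. A sequence was found for 774 of 779 genes, or 99.4%, and 16 of the named genes shared over 10% of their words. The annotation of that release is on another build, so none of its coordinates were used. Loci of 5 named entries overlapped another measured row. Coordinates are those of the deposited table, on mm9, with starts counted from 1.

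The steps were tested on simulated data. In a simulation of EtOH against 4OHT with 10845 genes, 200 of them changed 4-fold, 95% of the changed genes were found at 2-fold and 100% of those of at least 5 FPKM, with 0 unchanged genes passing. Of 100 unchanged lists of 25 genes 6 stood apart, and of 50 lists with 13 raised members 50 were found higher. The simulated noise was equal at all expression levels, independent between genes and small against the 2-fold limit. The simulation therefore checks that the steps run as meant. It does not show how they behave with the noise of low genes or with genes that change together. The alternatives tried were other q thresholds, filters, pseudocounts and scalings, random lists not matched on expression, and lists without shared members. Python 3.11.15 was used with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.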

Results

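Gene expression was measured by RNA sequencing in mouse bone marrow progenitors that carried an inducible form of the homeobox transcription factor Hoxa9. Lineage-depleted marrow of C57B6 mice had received 2 MIGR1 retroviruses. The first carried HA-tagged Hoxa9 fused to ER, the hormone-binding part of an estrogen receptor, and the other carried Flag-tagged Meis1, a homeobox partner of Hoxa9. With 4-hydroxytamoxifen (4OHT) the fusion stays in the nucleus, and without it nuclear Hoxa9-ER is lost. Cells transformed in IL3 and 100 nM 4OHT were washed and grown for 72 h either in 4OHT again or in ethanol (EtOH), its solvent. The question was which genes change when nuclear Hoxa9 is withdrawn from transformed progenitors.

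There were 2 samples, 4OHT and EtOH, and each stood for 2 biological replicates with 1 FPKM value per gene. How the replicates were combined is not known here. No replicate values were used here, so the FPKM values below have no replicate error. The differences have no replicate check beyond any that the authors' own test may hold. The FPKM values summed to 544802 in 4OHT and 591496 in EtOH. Read totals are not given by FPKM. The median lowest step of FPKM times locus length was 1.10 times as large in EtOH as in 4OHT. That step was taken inside a fixed window, which bounds its median, so it is only a rough hint of depth. Changes are given as log2((FPKM EtOH + 1)/(FPKM 4OHT + 1)), which understates the change of low genes, and a positive value is higher in EtOH. Values in parentheses after a gene name or an FPKM level are these log2 changes. "Rose" and "fell" are used of genes called at q of at most 0.05 in the authors' deposited table.

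Hoxa9 RNA was higher after 4OHT withdrawal, and so was RNA of Meis1 and of Esr1, the gene of estrogen receptor alpha. Hoxa9, at chromosome 6, 52174053 to 52177369 (mm9), rose from 476 to 892 FPKM, a log2 change of 0.90. Meis1, on chromosome 11, rose from 242 to 418 FPKM (log2 change 0.79), and Esr1, on chromosome 10, rose from 315 to 600 FPKM (log2 change 0.93). In the authors' deposited table the q-values were 2.03e-05 for Hoxa9, 9.32e-05 for Meis1 and 9.65e-05 for Esr1. The other 10 genes of the Hoxa cluster lay at or under 0.0193 FPKM, and 9 of them were listed at 0 in both conditions. RNA levels do not show where the fusion protein is in the cell, so these values check neither its nuclear loss nor the labels. Of the 6 Hox and TALE genes measured at 1 FPKM or more, 3 rose. Hoxa9 and Meis1 were also carried by the retroviruses, so their rise need not be one of the cells' own genes. The last was Pbx2, another homeobox partner, which went from 18.1 to 24.1 FPKM, with a q-value of 0.047 in the authors' deposited table. Pknox1, Pbx3 and Pbx4 did not pass, with log2 changes of -0.32, -0.35 and -0.37. The counts adjusted over the list alone were also 3 and 0, and the list median of 0.03 lay at percentile 65.51 of random lists. Over the 5 members that stand in no other list, which leaves out Meis1, the median turned to -0.32, at percentile 3.71.

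Loss of nuclear Hoxa9-ER was accompanied by large rises in genes of maturing granulocytes. The neutrophil genes S100a8 and S100a9, which encode the subunits of calprotectin, rose from 23.4 to 7149 and from 21.5 to 6386 FPKM. Prg2, the eosinophil major basic protein, rose from 108 to 4117 FPKM, and Mcpt8, a basophil protease, from 183 to 1685 FPKM. Of 22 stem and progenitor genes 10 fell and 5 rose; the receptor kinase Flt3 fell from 14.5 to 0.239 FPKM, and the stem cell antigen gene Prom1 rose from 1.69 to 17.0 FPKM. Of 37 genes of Myc function and ribosome production 26 fell, with a list median of -0.49, while cell cycle genes had a median of -0.02.

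The authors' deposited table tested 11865 genes, and 2672 of them, 22.5%, were called, with 1429 higher and 1243 lower in EtOH. Among the 11022 genes of at least 1 FPKM in either condition, 563 were at least 2-fold higher and 262 at least 2-fold lower. Over the 7820 genes of at least 5 FPKM in both conditions the median log2 change was -0.06, with quartiles of -0.24 and 0.14. Genes called and risen at least 2-fold held 2.36% of the FPKM sum in 4OHT and 11.4% in EtOH, and S100a8 and S100a9 together held 2.29% of it in EtOH. With EtOH scaled to the FPKM sum of 4OHT over the same genes, the median moved to -0.17, and 491 genes were at least 2-fold higher and 312 at least 2-fold lower. Of the 27 gene lists fixed beforehand, 12 had a median above the range of random lists, 2 below it and 12 inside it, and 1 had too few members.

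**Figure D1:**
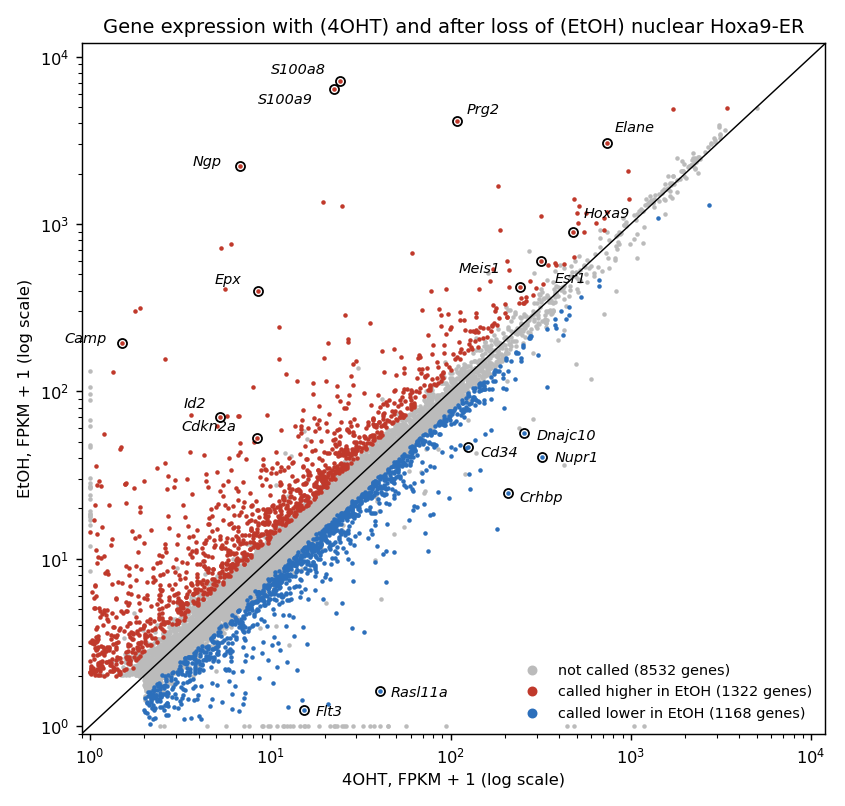
Each point is 1 of the genes with at least 1 FPKM in either condition, with FPKM + 1 in 4OHT on the x axis and in EtOH on the y axis, both log scales; the line marks equal values, red points were called higher in EtOH (1322) and blue points lower (1168). S100a8, S100a9, Ngp and Camp lie far above the line and Flt3, Rasl11a and Crhbp far below it; 69 genes on the edges were listed at 0 in 1 condition, and 64 of these carry symbols of small RNAs.

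Late neutrophil genes showed the largest rises. All 31 measured members of the list of secondary granule and late neutrophil genes rose, both over all genes tested and adjusted over the list alone, where 31 rose and 0 fell. The list median of 3.84 lay at percentile 100 of 10000 random lists matched on expression, of which 95% had medians between -0.18 and 0.07. Of the members under 1 FPKM in both conditions, Mmp25, Fpr1 and Fpr2 were not tested, and Mmp9, named after its values were seen, rose. Over all 35 matched members, without the filter, the median was 3.14. Ngp, a neutrophil granule protein, rose from 5.75 to 2225 FPKM (log2 change 8.37), ahead of S100a8 (8.20) and S100a9 (8.15). These S100 genes lie on chromosome 3 at 90472993 to 90473956 and 90496555 to 90499613 (mm9). Camp, which encodes the antimicrobial cathelicidin, rose from 0.507 to 194 FPKM (7.01), and 1100001G20Rik, a gene now named Wfdc21, from 1.61 to 156 FPKM (5.91). Chi3l3, a chitinase-like protein, rose from 0.772 to 299 FPKM (7.40), but 26.9% of its 50-base words also occur in transcripts of other genes, which leaves its own level uncertain. The same holds for the stefin A protease inhibitor cluster on chromosome 16, between 36156897 and 36408449 (mm9). There Stfa2l1 (7.38), BC100530 (7.07), Stfa1 (6.97), Stfa2 (6.60) and Gm5483 (6.12) rose, and between 11.0% and 25.1% of their words were shared.

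The list of primary neutrophil granule genes, meant to mark the promyelocyte stage, had smaller changes. Of 15 members 8 rose, 1 fell and 6 did not pass, against 9 and 2 adjusted over the list alone, and the median of 0.48 lay at percentile 99.96. Mpo, the myeloperoxidase gene, rose from 186 to 918 FPKM (2.29), and Elane, neutrophil elastase, from 736 to 3047 FPKM (2.05). Nkg7 rose from 14.2 to 75.9 FPKM (2.34). Hdc, the histamine-forming enzyme, rose from 93.5 to 409 FPKM (2.12), and it also stands in the list of basophil and mast cell genes. The member that fell, named after its values were seen, was the cathepsin G gene Ctsg, from 2722 to 1291 FPKM (-1.08).

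All 13 eosinophil genes of at least 1 FPKM rose, also adjusted over the list alone, with a median of 2.47 at percentile 100. The median was 1.29 with a pseudocount of 5 and 3.61 with 0.1. Of the members under 1 FPKM, the receptor gene Il5ra did not pass, at 0.478 and 0.448 FPKM, and Ear10 was listed at 0 in both conditions. Of the 13 genes that rose, Ear1 and the joint entry of Ear2 and Ear3 shared 57.4% and 41.5% of their words with other genes. Besides Prg2 (5.24), eosinophil peroxidase Epx rose from 7.50 to 395 FPKM (5.54), the chemokine Ccl6 from 24.0 to 1279 FPKM (5.68), and Prg3, which lies beside Prg2 on chromosome 2, from 10.1 to 155 FPKM (3.81). Among basophil and mast cell genes 18 of 21 rose, 1 fell and 2 did not pass, with 18 and 1 adjusted over the list alone. The median was 2.12 at percentile 100, and 1.42 over all 30 members without the filter. Of the members under 1 FPKM, the mast cell protease genes Mcpt1 and Mcpt9 were listed at 0 in both conditions. Mcpt2, Mcpt4 and Tpsab1 were not tested. The mast cell tryptase Tpsb2 rose from 10.2 to 242 FPKM (4.44). The cytokine genes Il13 and Il4, neighbours on chromosome 11, rose from 0.763 to 25.6 FPKM (3.91) and from 1.34 to 33.6 FPKM (3.88). Ctsg, which also stands in this list, was the member that fell.

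Most monocyte and macrophage genes of at least 1 FPKM in either condition rose, some of them from low values. Of 26 members 18 rose, 3 fell and 5 did not pass, against 18 and 4 adjusted over the list alone, and the median was 0.95 at percentile 100. It was 0.34 with a pseudocount of 5, 1.53 with 0.1 and 0.43 over all 46 members without the filter. Among the low members, Csf1r rose from 0.347 to 2.10 FPKM and Mrc1 from 0.0839 to 1.92 FPKM. The more abundant Ly6c2, at 3104 and 3463 FPKM with 14.4% of its words shared, and Cd68, at 41.8 and 30.6 FPKM, did not pass. These genes were named after their values were seen. Thbs1, the gene of the matrix protein thrombospondin, rose most, from 4.62 to 408 FPKM (6.19). The tetraspanin Cd9 rose from 27.7 to 145 FPKM (2.35). Lysozyme gene Lyz2 rose from 40.5 to 174 FPKM (2.08) and the integrin gene Itgam from 16.2 to 112 FPKM (2.71), with 15.4% and 66.3% of their words shared with other genes. The members that fell, named after their values were seen, were Pld4 (-1.78), Emr1 (-0.98), which encodes the macrophage antigen F4/80, and Axl (-0.43).

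Most measured phagocyte oxidase and pathogen receptor genes rose as well. In that list 24 of 32 members rose, 2 fell and 6 did not pass, against 25 and 2 adjusted over the list alone, with a median of 1.01 at percentile 100. Cybb, a subunit of the phagocyte oxidase, rose from 0.244 to 7.47 FPKM (2.77), the complement receptor C5ar1 from 0.327 to 12.03 FPKM (3.30) and the lectin Clec4a2 from 0.160 to 14.5 FPKM (3.74). Cd300lf rose from 5.77 to 42.3 FPKM (2.68), and its locus overlaps Rab37, at 22.5 and 24.9 FPKM, so that reads could not be assigned with certainty. The related lectins Clec4e (-1.99) and Clec4d (-0.93), named after their values were seen, fell.

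Of 29 inflammatory cytokine and NF-kB genes, 19 rose, 2 fell and 8 did not pass, against 21 and 3 adjusted over the list alone, with a median of 1.07 at percentile 100, which was 0.40 with a pseudocount of 5. After Ccl6 the largest rises were in Il1b, from 1.70 to 30.003 FPKM (3.52), Il6, from 20.03 to 193 FPKM (3.20), and the interleukin antagonist Il1rn, from 1.92 to 25.8 FPKM (3.20). The Il1b locus overlaps Gm14047, at 1.08 and 3.21 FPKM. The members that fell, Tnfsf9 (-0.98) and Sod2 (-0.45), were named after their values were seen. Cytokine receptor and adhesion genes had 20 of 30 members risen, 4 fallen and 6 that did not pass, against 21 and 4 adjusted over the list alone, and a median of 0.68 at percentile 100. The decoy receptor Il1r2 rose from 5.82 to 47.8 FPKM (2.84), the chemokine receptor Ccr1 from 5.61 to 40.7 FPKM (2.66), and Csf3r, the receptor of granulocyte colony-stimulating factor, from 10.3 to 32.4 FPKM (1.57), with 10.5% of its words shared. Il10ra (-1.02), Itga4 (-0.80), Itgb1 (-0.53) and Itgal (-0.44), named after their values were seen, fell.

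Myeloid transcription factor genes were higher on balance. Of 33 members 16 rose, 3 fell and 14 did not pass, against 17 and 4 adjusted over the list alone, with a median of 0.36 at percentile 100, which was 0.21 with a pseudocount of 5. Id2, an inhibitor of helix-loop-helix factors, rose from 4.25 to 69.3 FPKM (3.74). Klf2 rose from 6.17 to 20.8 FPKM (1.60) and the early response gene Egr1 from 23.0 to 58.8 FPKM (1.32). Irf8, a factor required for monocyte and dendritic cell development, fell from 4.09 to 0.751 FPKM (-1.54). The others that fell, named after their values were seen, were Id3 (-0.84) and Atf3 (-0.67).

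Stem and progenitor genes were lower on balance. Of 22 members 5 rose, 10 fell and 7 did not pass, against 6 and 12 adjusted over the list alone, and the median of -0.36 lay at percentile 0.00 of random lists, whose 95% range was -0.21 to 0.10. Flt3 had the largest fall of the list (-3.64), followed by Sox4, a transcription factor gene, from 9.54 to 2.38 FPKM (-1.64), and Cd48, a surface antigen gene, from 166 to 57.8 FPKM (-1.51). Prom1, which encodes the antigen CD133, went the other way (2.74). Meis1, among those that rose, was also carried by a retrovirus, and without it the list median was -0.37 at percentile 0.02.

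Genes described as targets of Hoxa9 or Meis1 changed in both directions. Of 26 members 11 rose, 10 fell and 5 did not pass, against 11 and 11 adjusted over the list alone. The list draws on knowledge of published work, part of it on cells of this kind, so its count is not independent evidence of direction. Its median of -0.03 lay at percentile 67.17, but the 11 members that stand in no other list had a median of 0.23 at percentile 98.82. Dnajc10, a chaperone of the endoplasmic reticulum, fell from 254 to 55.3 FPKM (-2.18). Id2 and Cdkn2a rose, and Flt3 fell.

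The 12 largest falls among genes of at least 5 FPKM lay mostly outside the lists. Rasl11a, a small GTPase gene, fell most, from 39.6 to 0.609 FPKM (-4.66), and Pde11a, a cyclic nucleotide phosphodiesterase, from 19.99 to 0.361 FPKM (-3.95). Among more abundant RNAs, Nupr1, a stress-induced nuclear protein, fell from 319 to 39.7 FPKM (-2.98), Crhbp, which encodes the binding protein of corticotropin-releasing hormone, from 208 to 23.8 FPKM (-3.08), and Gm11428 from 179.8 to 14.04 FPKM (-3.59). Btn1a1 (-3.26), Rgl1 (-3.18), the ATP-gated channel P2rx3 (-2.87), Tmem176b (-2.76) and Frmd5 (-2.71) also fell. The monoamine transporter Slc18a1 fell from 13.97 to 0.426 FPKM (-3.39), and its locus overlaps Atp6v1b2, at 71.2 and 54.7 FPKM.

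Most cell cycle genes did not pass the test, while several inhibitors of cyclin-dependent kinases rose. Of 50 cell cycle genes 2 rose, 1 fell and 47 did not pass, with the same counts of 2 and 1 adjusted over the list alone, and the median of -0.02 lay at percentile 79.56. The quartiles were -0.15 and 0.13, and Gins2, a member that did not pass, had a failed test. The members called were the E2F factors E2f2, from 5.31 to 14.4 FPKM (1.29), and E2f8, from 47.7 to 27.2 FPKM (-0.79), and the mitotic kinesin Kif23, from 12.3 to 19.1 FPKM (0.59). In the list of cell cycle inhibitors and cyclins D and E 10 of 22 members rose, 2 fell and 10 did not pass, against 10 and 3 adjusted over the list alone, with a median of 0.38 at percentile 100. Cdkn2a, the locus of p16 and p19 Arf on chromosome 4 at 88920377 to 88940523 (mm9), rose from 7.43 to 51.6 FPKM (2.64). Its neighbour Cdkn2b, at 88952198 to 88956941, rose from 4.12 to 20.2 FPKM (2.05). Btg2 (1.47) and Gadd45b (0.75), both antiproliferative genes, rose as well. Not all risers were inhibitors. The cyclin genes Ccnd3 and Ccne1, named after their values were seen, also rose, with q-values of 0.00058 and 0.0168 in the authors' deposited table. The kinase genes Cdk6 (-0.63) and Cdk4 (-0.45), named after their values were seen, fell.

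Apoptosis genes had 8 of 28 members risen, 1 fallen and 19 that did not pass, against 11 and 3 adjusted over the list alone, with a median of 0.26 at percentile 100, which was 0.15 with EtOH scaled to the 4OHT sum. The survival gene Bcl2 fell from 25.5 to 9.96 FPKM (-1.27), and Bcl2l11, which encodes the death-promoting protein Bim, rose from 2.39 to 7.27 FPKM (1.29). The paralogs Bcl2a1b (2.76) and Bcl2a1a (2.04) rose, but 79.2% and 69.0% of their words are shared with other genes.

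Most genes of Myc function and ribosome production fell. Of 37 members 26 fell, 0 rose and 11 did not pass, against 31 and 0 adjusted over the list alone. Myc itself was among the 11 that did not pass. The median of -0.49 lay at percentile 0.00, and 95% of the random lists lay between -0.17 and 0.06. The spermidine synthase gene Srm fell from 167 to 88.9 FPKM (-0.90), the nucleolar genes Nolc1 from 44.2 to 25.6 FPKM (-0.76) and Rrp9 from 29.0 to 17.2 FPKM (-0.72). Odc1, the ornithine decarboxylase gene, fell from 153 to 84.2 FPKM (-0.86), with 24.3% of its words shared.

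**Figure D2:**
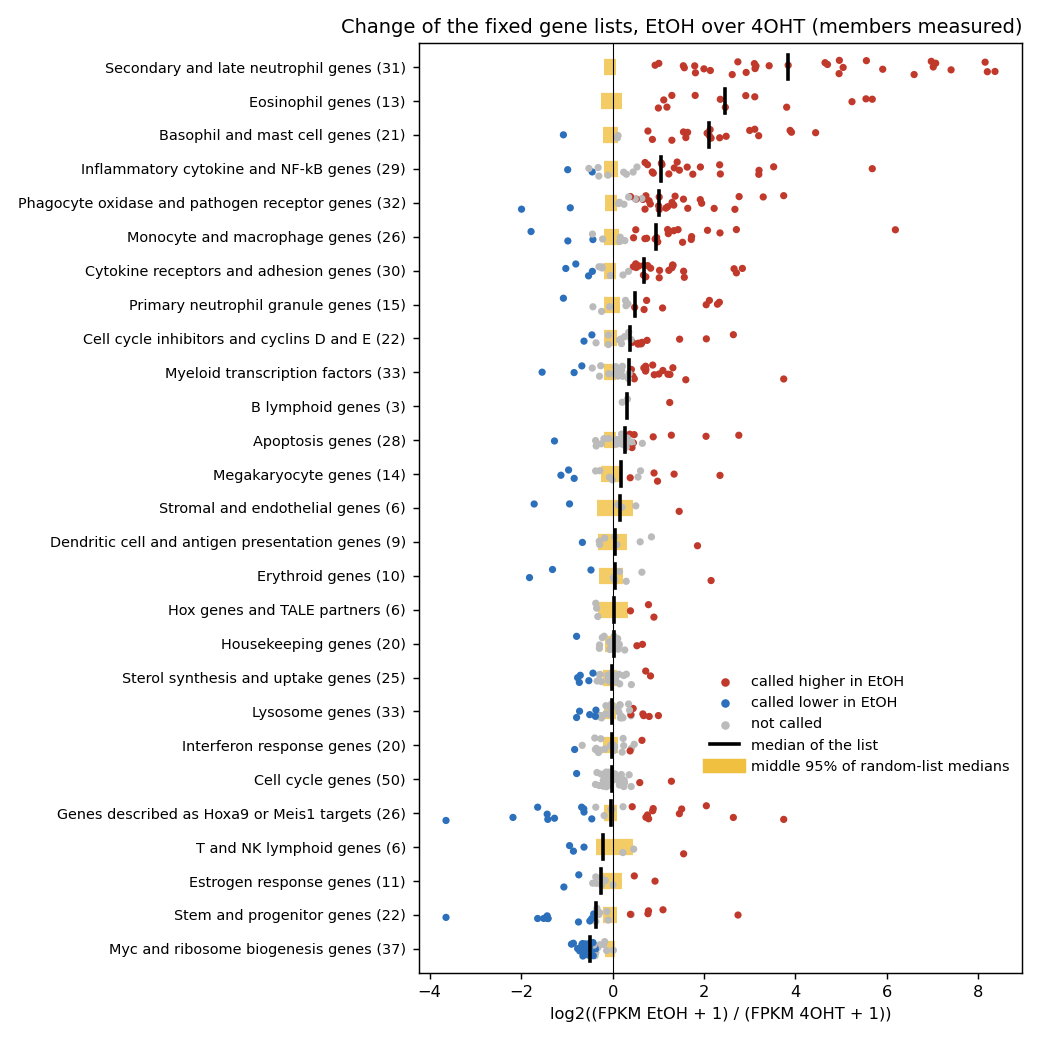
Each row is a gene list fixed beforehand, with the number of measured members in parentheses, and each point is 1 member by its log2 change on the x axis (red called higher in EtOH, blue called lower, grey not called; vertical jitter only separates points). Black bars are list medians and yellow bands hold 95% of the medians of random lists; late neutrophil (3.84), eosinophil (2.47) and basophil and mast cell genes (2.12) lie farthest to the right, and Myc and ribosome biogenesis genes (-0.49) lowest.

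Markers of other blood lineages and of stroma moved in both directions and by less. Of 10 erythroid genes 1 rose, 3 fell and 6 did not pass, against 2 and 3 adjusted over the list alone, with a median of 0.04 at percentile 80.42. Gata1, a transcription factor also used in basophils, mast cells and eosinophils, rose from 1.60 to 10.6 FPKM (2.15), whereas Car2, a carbonic anhydrase gene, fell from 37.2 to 26.5 FPKM (-0.47) and the joint beta globin entry of Hbb-b1 and Hbb-b2 from 197 to 78.7 FPKM (-1.31). The globin entry overlaps a separate entry for Hbb-b2, so its level is uncertain. Of 14 megakaryocyte genes 5 rose, 3 fell and 6 did not pass, against 6 and 4 adjusted over the list alone, with a median of 0.19 at percentile 98.21. Without members that stand in another list, such as Cd9, the median was -0.0050 and the percentile 70.94, and with EtOH scaled to the 4OHT sum the median was 0.07. Gfi1b rose from 1.76 to 6.004 FPKM (1.35) and Vwf from 0.229 to 1.43 FPKM (0.98), while Zfpm1, a cofactor of Gata1, fell from 11.4 to 4.68 FPKM (-1.13).

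Of 6 measured T and NK lymphoid genes 1 rose, 3 fell and 2 did not pass, against 2 and 3 adjusted over the list alone, with a median of -0.20 at percentile 14.20. Over the 5 members that stand in no other list the median turned to 0.23, at percentile 87.61. Thy1, also counted among the stromal genes, fell from 418 to 217 FPKM (-0.94), and Lck (-0.86) and Tcf7 (-0.63) fell as well. B lymphoid genes had 3 measured members, too few for a percentile, of which Il7r rose from 0.0582 to 1.52 FPKM and 2 did not pass, with 1 and 0 adjusted over the list alone. Among 6 stromal and endothelial genes 1 rose, 2 fell and 3 did not pass, as adjusted over the list alone, with a median of 0.16 at percentile 84.42. Vcam1 rose from 0.0596 to 1.91 FPKM (1.46) and Pdgfrb fell from 7.99 to 1.74 FPKM (-1.72). In the list of dendritic cell and antigen presentation genes 1 of 9 rose, 1 fell and 7 did not pass, as adjusted over the list alone, with a median of 0.05 at percentile 71.91. The median turned to -0.17, at percentile 19.4, without members that share sequence, and to -0.06 at a minimum of 5 FPKM. Cd74, the invariant chain, rose from 0.690 to 5.12 FPKM (1.86), and H2-DMa, a class II chaperone, fell from 35.2 to 21.9 FPKM (-0.66).

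Sterol, estrogen and interferon lists had medians inside the range of random lists. Of 25 sterol genes 2 rose, 5 fell and 18 did not pass, against 3 and 5 adjusted over the list alone, with a median of -0.02 at percentile 75.55. Sc5d rose (0.83) and Insig1, a brake on sterol synthesis, fell (-0.73), as did Idi1 (-0.76), while Fdps rose (0.72), with shared words of 17.7% in Idi1 and 26.2% in Fdps. Of 11 estrogen response genes 2 rose, 2 fell and 7 did not pass, against 2 and 4 adjusted over the list alone. Apart from Esr1, Rara rose (0.48), and the potassium channel Kcnk5 (-1.07) and carbonic anhydrase Car12 (-0.74) fell. The list median of -0.25 lay at percentile 3.43, and it passed the lower limit with a pseudocount of 5, at percentile 1.32, and without Esr1, at percentile 1.37. Without the filter on low values, over 22 members, the median was 0 at percentile 54.5.

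Of 20 interferon response genes 2 rose, 1 fell and 17 did not pass, against 1 and 1 adjusted over the list alone, with a median of -0.02 at percentile 65.52. The RNA sensor Ifih1 rose (0.64) and Oas3 fell (-0.83). Of 33 lysosome genes 6 rose, 5 fell and 22 did not pass, against 8 and 5 adjusted over the list alone, with a median of -0.02 at percentile 74.73. Without the filter on low values the median was 0.12 and the percentile 99.65. Ctsh rose (1.00), and Gusb (-0.79) and Gaa (-0.72) fell. Among 20 housekeeping genes 2 rose, 1 fell and 17 did not pass, against 1 and 1 adjusted over the list alone, with a median of 0.03 at percentile 66.47. With EtOH scaled to the 4OHT sum, the small positive medians of the housekeeping, Hox, erythroid and dendritic cell lists turned to -0.09, -0.08, -0.04 and -0.06. Centred on the median gene, the small negative medians of the cell cycle, sterol, interferon, lysosome and described target lists turned to 0.04, 0.05, 0.04, 0.04 and 0.04. The actin genes Actg1, with 37.4% of words shared, and Actb rose from 643 to 1012 FPKM and from 970 to 1403 FPKM, and Gusb fell from 153 to 88.1 FPKM.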

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

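The search among genes whose test had failed was chosen after the test status of the rows had been seen, and no further test was run on its results. The authors' deposited table marks 21 genes with a failed test, and 19 of them reached 1 FPKM in either condition. Among these, Jak2, the kinase that acts below the IL3 receptor, on chromosome 19 at 29326318 to 29387570 (mm9), was at 11.0 FPKM in 4OHT and 41.7 FPKM in EtOH, a log2 change of 1.83. It was singled out because the comparisons of called genes leave such rows out. No other gene of the 19 was at least 2-fold higher in EtOH. Gsn, the gene of the actin-severing protein gelsolin, was at least 2-fold lower, at 708 FPKM in 4OHT and 288 FPKM in EtOH (log2 change -1.30), and no other of the 19 was. Neither change has a test behind it. Why the tests failed is not given, so the FPKM values of these rows may themselves be less certain.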

How the results depend on the processing

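Leaving out members with shared sequence, leaving out Hoxa9, Meis1 and Esr1, scaling EtOH to the 4OHT sum, scaling lists up to a fixed common sum and the authors' second call were chosen after seeing the data. No paired analysis was possible because the table gives 1 value per condition and no replicate columns. For that reason leave-one-out and the replicate block were not run. Of 259 alternative percentiles for 26 lists, 253 stayed on their side of the limits, 5 moved past a limit, 1 fell short of it and 0 reversed. Of the 14 lists that stood apart, 13 did so under every alternative run, but percentiles at 0 or 100 cannot show smaller moves. Their medians moved more, from 2.70 to 5.47 for late neutrophil, 1.29 to 3.61 for eosinophil, 0.34 to 1.53 for monocyte and 0.40 to 1.47 for inflammatory genes, each lowest with a pseudocount of 5 and highest with 0.1. The list that did not stay apart was the megakaryocyte list, at percentile 70.94 over members of 1 list only. Over such members the list of described Hoxa9 or Meis1 targets moved to 98.82 and the lysosome list to 99.59, and without the filter the lysosome list lay at 99.65. The estrogen response list moved to 1.32 with a pseudocount of 5 and to 1.37 without Esr1, and lay between 2.84 and 54.5 under its other alternatives, the latter without the filter. Lists left with too few members gave no value in 4 cases, the Hox list without Hoxa9 and Meis1 and the Hox, T and NK, and stromal lists at 5 FPKM.

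Counts depended on thresholds by construction. Genes called lower numbered 793 at a q of 0.01, and at a ratio of at least 2 there were 774 called higher and 420 called lower. Genes at least 2-fold lower numbered 407 with a pseudocount of 0.1 and 145 with 5, where 318 were higher. With both conditions scaled up to a fixed common sum, which also makes the pseudocount and the filter smaller against the values, 401 were at least 2-fold lower. With EtOH scaled to the 4OHT sum alone 312 were. The unknown read depth limits low genes most, since a change of a few fragments moves them far.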

Other observations

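Families of gene symbols were compared after the lists had been seen, and of the tests below that of reads shared between gene copies was set before its result was known, the others after. Among 163 families with at least 8 measured members, 18 had medians above the limit for random lists and 10 below. Lists of genes that change independently would give about 4.08 at each side. Members of a family can change together, so the counts of 18 and 10 cannot be tested against that number. Examples of families on either side are given here. The Klf family of zinc finger transcription factors had a median log2 change of 0.66, with 6 of 10 members called higher and 0 lower. The tumour necrosis factor receptor family, Tnfrsf, had 8 of 14 members called higher and a median of 0.74. Rgs genes, which curb G protein signalling, had a median of 0.57, with 6 of 10 called higher and 2 lower. Annexins (Anxa) had 5 of 9 called higher (median 0.49), inositol phosphatases (Inpp) 5 of 10 (median 0.45), and Dennd genes, activators of Rab proteins, 6 of 10 (median 0.39). C-type lectins (Clec) were split, with 8 of 14 called higher and 5 lower.

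Some other families had lower medians. Nucleoporins (Nup) had a median of -0.29, with 5 of 20 members called lower and 0 higher. Mitochondrial ribosomal proteins of the large subunit (Mrpl) had a median of -0.20, with 6 of 47 called lower, and RNA polymerase subunits (Polr) a median of -0.24, with 4 of 28. For comparison, of all 11022 genes of at least 1 FPKM in either condition 1322 were called higher and 1168 lower. Small nucleolar RNAs (Snord) had a median of -0.45, but 0 of 47 were called, and RNAs that short are poorly measured by such libraries. Cytoplasmic ribosomal proteins stayed inside the random range, with medians of 0.085 for Rps (41 genes, 4 called higher and 0 lower) and 0.062 for Rpl (47 genes, 1 called higher and 0 lower), as did the Cox, Ndufa, Psma, Psmb, Psmd and Eif families. Eif genes lay near the lower limit, with a median of -0.14 at percentile 4.98 and 9 of 54 called lower and 0 higher. With EtOH scaled to the 4OHT sum the median gene moves to -0.17, so the directions of Rps and Rpl are open. These family medians rest on 1 value per condition with no replicate check. Of the genes in these families, 3 Polr, 3 Tnfrsf, 7 Clec, 2 Klf and 1 annexin gene also stand in a fixed list.

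Hoxa9, Meis1 and Esr1 RNA were higher in EtOH, although EtOH is the condition in which, by the design, the fusion is lost from the nucleus. A scaling shift is argued against, since the median change of well-expressed genes was -0.062 and the 3 genes rose by 0.79 to 0.93. The Hoxa9 reads may come from the retroviral construct, since Hoxa9 was at 476 and 892 FPKM while no other Hoxa gene exceeded 0.0193 FPKM. On that reading the rise of Hoxa9 would be a rise of retroviral transcripts, and its biological cause was not tested. Whether the Meis1 reads come from its retrovirus, or the Esr1 reads from the fusion, was not tested either.

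Granule genes of neutrophils, eosinophils and basophils rose together. A loss of undifferentiated cells alone would raise the markers of the other cell types that the culture held. The 38 erythroid, megakaryocyte, lymphoid and stromal markers had a median of 0.18, with quartiles of -0.45 and 0.60, against 2.47 for eosinophil genes. This comparison cannot decide, because nothing shows that mature cells of those lineages were present. Only 3 of 21 B lymphoid and 6 of 26 T and NK genes reached 1 FPKM. Thy1, counted among the markers, was at 418 FPKM in 4OHT. A loss of undifferentiated cells therefore stays open. Reads shared between gene copies are argued against as the whole cause, since the late neutrophil list without members that share sequence had a median of 3.28. An effect of 4OHT that does not pass through the fusion cannot be told apart from loss of Hoxa9, because 0 samples lacked the construct. Loss of nuclear Hoxa9, the biological difference the design names, stays open and was not tested apart from 4OHT.

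Ribosome biogenesis genes were lower in EtOH while cell cycle genes were level. A larger share of granule RNAs would shift all other genes alike, but after centring on the median gene the ribosome list still had a median of -0.43 and an upper quartile of -0.31. Fewer cycling cells are argued against, since the cell cycle list had a median of -0.0235 and a lower quartile of -0.15, above the ribosome list's -0.49. Loss of nuclear Hoxa9 stays open here too and was not tested apart from 4OHT.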
